A study of Scophthalmus maximus with 32 samples.

How the data were processed

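Spleen RNA of turbot was hybridized on 32 oligo-microarrays, on 4 slides of 8 arrays each. Per the labels, fish were injected with the bacterium Aeromonas salmonicida or left as uninfected controls, spleens were taken after 3 days (72 h) and pooled, and total RNA was extracted from the pools. The series text gives 1 pool of 5 control fish and 2 pools of 5 infected fish. It describes 24 arrays, whereas the deposited set holds 32. The labels do not say which pool, extraction or labelling an array belongs to, so arrays were treated as replicates of their group. Their spread mixes technical steps with, in the infected group, any difference between pools. The adjusted p values below describe these pools and not the spread between fish.

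Of the 32 arrays, 22 carried 1 dye (one-colour, Cy3, 0.2 ug RNA per labelling), 15 of infected and 7 of control RNA. The other 10 carried infected and control RNA together (two-colour, 50 ng RNA per labelling), 5 with infected RNA in Cy5 and 5 with infected RNA in Cy3. Arrays were numbered within their group in the order of the labels.

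Each array held 14116 features, of which 13580 were spots of 2716 fish probes with 5 spots per probe. A further 459 were positive and 77 negative control spots. Probes were 54 to 60 bases long. No probe carried a gene name or a public identifier, and the reference table of gene names could not be joined to the probe identifiers. Probes are therefore reported by identifier, and the planned shifts of gene lists were not tested.

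The spot intensity values were made by the authors with Agilent Feature Extraction 9.5.1.1, per the file headers. One-colour processed intensity had a fitted background surface subtracted and was divided by a detrending surface, per the file headers. Two-colour processed intensity was in addition normalized between the dyes with linear and lowess steps, per the file headers. The log ratios in the two-colour files are log10 of Cy5 over Cy3, per the file headers, and were not tested. The deposited value table held, for one-colour arrays, the processed intensity itself: 256421 values were compared and the largest log2 difference was 0. None of these values lay on an outlier spot or on a spot not well above background. For two-colour arrays the deposited values were log2 ratios, whose normalization steps, centring and direction no label states. They correlated with infected over control at -0.942 to -0.884, so they ran as control over infected, and were turned before use. Their medians per array ran from -0.027 to 0.064, and the medians of the one-colour columns ran from 1171 to 7506.

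One-colour values were log2 of the processed intensity minus the 75th percentile of each array. Two-colour values were corrected with normexp (offset 50), normalized with loess within arrays and with Aquantile between arrays, as the series text names for the study. Control spots had weight 0 in loess and were left out of the tests, as were outlier spots, and the spots of a probe were averaged. A one-colour probe was tested if it was well above background on at least 7 of the 22 arrays, which held for 2626 probes. A two-colour probe was tested if it was well above background in either channel on at least 5 of the 10 arrays, which held for 2617, and 2613 probes were tested both ways. A probe counted as well above background on an array with at least 3 such spots. No fish spot was saturated. The number of arrays limits the precision.

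Tests were made with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with files read by the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9. A probe was called at a Bonferroni-adjusted p under 0.05 and a fold over 1.5, and the grid of p 0.05 and 0.01 with folds over 1.5, 2 and 3 follows the series text. The two-colour fit had an infection term, coded by dye orientation, and a dye term. The 2 orientations were also fitted separately. The share of common calls was the number of probes called in both sets with the same sign over the number called in either. The difference between the one-colour and the two-colour log2 ratio was tested against the root of the summed squared standard errors, with degrees of freedom summed. The variance between slides was split from the rest by the method of moments within the infected one-colour arrays. Slides and scans were told apart from the file headers. Slides 1 and 2 were scanned together, and slides 3 and 4 each on their own.

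The rule for named probes allowed at most 2 that rose and 2 that fell: those with the largest one-colour change among probes called with the same sign in both labelling approaches. The comparisons, tests, this rule and most alternatives were fixed before the data were examined.

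The fits and calls were tested on simulated probe values with 100 probes changed 2-fold and 100 changed 3-fold. Noise was drawn separately for each probe and array, at the level of normalized values. Background correction, scaling and averaging of spots were thus not run. The recovery below also does not cover arrays that deviate together across probes. The one-colour step, over 2626 probes, recovered 88% of the former and 91% of the latter. The two-colour infection step, over 2617 probes, recovered 98% and 100%, and its dye step 96% and 100%. The test of the difference between approaches, over 2613 probes, recovered 93% and 97%. No unchanged probe was called. With 50% of the variance set between slides, the median share came out as 43.3%.

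Alternatives covered quantile scaling, normexp and other background corrections, the filter on dim probes, outlier spots, the deposited table, slide and replicate number as blocks, single slides for one-colour arrays, array weights, the correction for multiple tests, thresholds, the dye term, and leaving out single arrays. Added after the data had been seen were fits without arrays that stood apart, the median of a probe's spots, scan as a block, single slides for two-colour arrays, and the 14 arrays of the replicate block fitted without it. Also added were slide as a block for the difference between approaches and dim patches left out (cells of an 8 by 6 grid whose spots fell by over 0.3 on the log2 scale).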

Results

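The data were spot intensities of 2716 turbot probes on 22 one-colour and 10 two-colour arrays. The study asked how much arrays vary at each technical level and between slides, how far the choice of dye biases the signal, and how one-colour and two-colour labelling compare, with infected against control spleen as the contrast. Slide 1 held 7 infected and 1 control one-colour arrays. Slide 2 held 3 infected and 3 control one-colour arrays and 1 two-colour array of each orientation. Slide 3 held 3 infected and 1 control one-colour arrays, slide 4 held 2 of each, and both had 2 two-colour arrays of each orientation.

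The 75th percentile of the one-colour signal ran from 9921 to 19080 intensity units on infected arrays. On control arrays it ran from 2890 to 13691. Control 2, 4 and 7 had the lowest values of all one-colour arrays, at 2890, 7146 and 7854, and infected 7 stood at 13079. The mean log2 signal over a set of positive control probes was also lowest on control 2, 4 and 7. It was 11.69, 13.46 and 13.63 there, and 13.69 on the next array, infected 9. The two-colour arrays had 75th percentiles of 3008 to 3499 in Cy3 and 3032 to 3550 in Cy5. Between 91.6% and 98.2% of probes were well above background on each one-colour array, and 94.8% to 97.2% on each two-colour array. On all 22 one-colour arrays 2461 probes were well above background.

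Replicate one-colour arrays were compared by Pearson correlation of log2 levels across probes, which are not independent replicates. The median over pairs was 0.997 for the 15 infected arrays, 0.998 on the same slide and 0.997 on different slides. It was 0.976 for the 7 control arrays, 0.969 on the same slide and 0.977 on different slides. Pairs of an infected and a control array had a median of 0.974. The control arrays thus correlated with one another about as far as with infected arrays. Without control 2, 4 and 7 the control median was 0.997, and those arrays had median correlations with their group of 0.961, 0.972 and 0.977, against 0.986 to 0.987 for the other controls. Infected 7 stood at 0.973, with the other infected arrays at 0.994 to 0.999. For log2 ratios of two-colour arrays the median was 0.917 with infected RNA in Cy5 and 0.923 with infected RNA in Cy3. Same-slide pairs reached 0.976 and 0.954, and pairs on different slides 0.869 and 0.863. Both two-colour arrays of slide 2 stood lowest, at 0.793 and 0.774. The standard deviation among spots of a probe was 0.33 on the log2 scale on control 4, against 0.06 to 0.08 on the other one-colour arrays. On control 4 a central patch of 1122 spots, 8.26% of the fish spots, was dim, and its dimmest cell fell by 1.34 on the log2 scale.

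**Figure D1:**
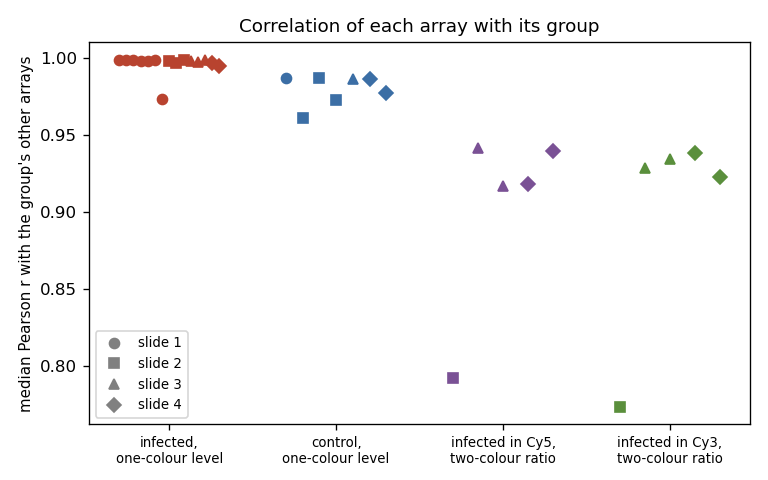
Median Pearson correlation (vertical axis, no unit) of each array with the other arrays of its group, by group (horizontal axis) and slide (symbol). Infected 7 at 0.973, control 2, 4 and 7 at 0.961, 0.972 and 0.977, and both two-colour arrays of slide 2 at 0.793 and 0.774 lie below the rest of their groups.

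**Figure D2:**
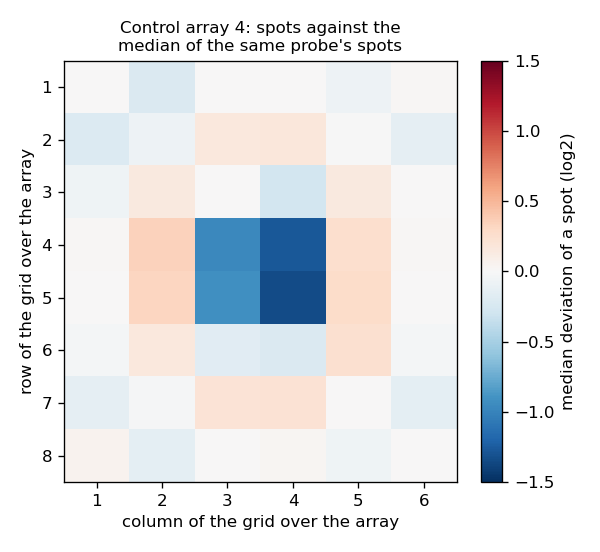
Median log2 deviation (colour) of the spots of control 4 from the median of the same probe's spots, in cells of an 8 by 6 grid over the array (both axes, cell number). The central cells are dim, down to -1.34.

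Within the infected one-colour arrays, slide took a median of 17.5% of a probe's variance, with quartiles of 0% and 46.0%. For 33.7% of probes the estimate was 0. The median residual standard deviation was 0.09 on the log2 scale. Without infected 7 the median share of slide was 32.7%. The shares of biological pool, extraction, labelling and hybridization could not be estimated, since the labels do not give them.

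The one-colour comparison asked which probes differed between infected and control spleen. Of 2626 probes tested, 117 were higher and 119 lower in infected arrays, 8.99% in all. Log2 ratios had a median of -0.07 and a standard deviation of 0.52. The called probes that were higher had a median fold of 1.89, and the lower ones 1.69. Over 3-fold, 29 were higher and 3 lower. Of the 29, 25 were well above background on all 7 controls, and the size of the rise of the rest was not settled. With normexp 22 were higher over 3-fold, and 18 probes passed that fold in both one-colour settings and in the two-colour fit. Of all 2626 tested probes, 147 had all 15 infected arrays above all 7 controls and 275 had all of them below, and 81 and 84 of these were called. Were the 22 arrays independent, 0.00117% would lie apart by chance in either direction together. The arrays repeat 1 control pool and 2 infected pools, however, so a difference between pools alone could set them apart. In 4 equal sets of the tested probes ordered by control level, from dim to bright, 46, 27, 23 and 21 were higher and 32, 36, 20 and 31 lower. With slide as a block, 123 were higher and 125 lower. Fitted alone, slides 1, 2, 3 and 4 called 33, 15, 69 and 3 higher probes and 48, 0, 16 and 0 lower ones. At an unadjusted p under 0.05 in limma, slides 2 and 4 had 575 and 294 lower probes. The number of arrays did not order the calls of single slides. Slide 3 held 3 infected and 1 control one-colour arrays and called more than slide 2, with 3 of each. Of the arrays with low correlations to their group, control 2 and 4 lay on slide 2 and control 7 on slide 4. Infected 7 lay on slide 1. Whether these arrays lowered the calls was not tested. The deposited table of the same arrays, scaled on the 678 spots it held on every array, gave 180 higher and 74 lower, so that 70.9% of calls were higher against 49.6%. Without control 2, 4 and 7 and infected 7, 210 were higher and 198 lower, and 205 of the 236 probes called on all arrays were among them.

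Signed values are infected over control, opposite to the deposited two-colour table. Probe R1__466 (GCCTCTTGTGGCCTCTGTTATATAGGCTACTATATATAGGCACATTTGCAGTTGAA) had a one-colour ratio of 5.29 ± 0.25 (SE, 15 and 7 arrays) on the log2 scale, with a Bonferroni-adjusted p of 9.02e-13. It was well above background on 1 of the 7 control arrays and on all 15 infected arrays, so the size of its rise was not settled and depended on the background correction. With normexp its one-colour ratio was 3.02, and in the two-colour fit it was 2.83 ± 0.05 (SE, 10 arrays). Probe R1__450 (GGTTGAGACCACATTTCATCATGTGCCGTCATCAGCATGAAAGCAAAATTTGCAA) rose by 4.79 ± 0.42, 27.6-fold, with a Bonferroni-adjusted p of 3.00e-07, by 4.26 with normexp, and by 3.75 ± 0.07 in the two-colour fit. Of these 2 probes, R1__450 had the larger ratio with normexp and in the two-colour fit, and R1__466 the larger one in the one-colour fit without it. Its control levels ran from -6.38 to -5.64 relative to the 75th percentile on 6 arrays and stood at -1.63 on control 2. Without control 2, 4 and 7 and infected 7 it rose by 5.59.

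Probe R1__2884 (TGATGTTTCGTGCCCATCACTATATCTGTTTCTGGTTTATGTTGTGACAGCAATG) fell by 2.03 ± 0.15 (SE) on the log2 scale, 4.09-fold, with a Bonferroni-adjusted p of 1.57e-08, and fell by 1.85 ± 0.06 in the two-colour fit. Probe R1__1137 (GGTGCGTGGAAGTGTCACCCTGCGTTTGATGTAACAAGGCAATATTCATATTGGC) fell by 1.72 ± 0.14, 3.30-fold, with a Bonferroni-adjusted p of 7.92e-08, and fell by 1.35 ± 0.05 in the two-colour fit. For each of these 4 probes, all 15 infected arrays lay on one side of all 7 controls, and the ratio had the same sign on 10 of 10 two-colour arrays.

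**Figure D3:**
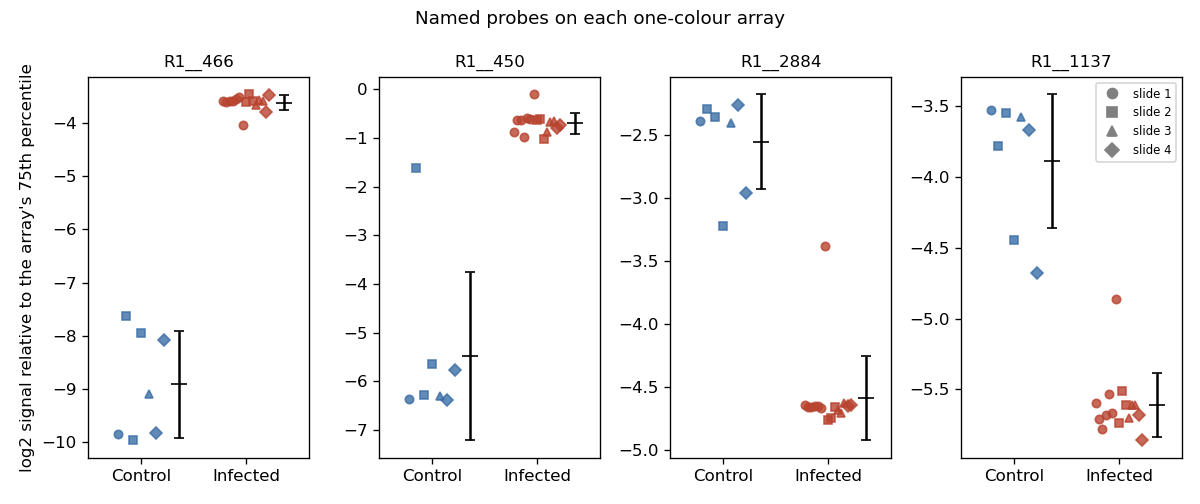
Log2 signal relative to the array's 75th percentile (vertical axis) of the 4 named probes on each one-colour array, by group (horizontal axis) and slide (symbol), with mean and standard deviation as bars over 15 infected and 7 control arrays. All infected arrays lie on one side of all controls, and control 2 stands at -1.63 for R1__450, apart from the other controls.

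In the two-colour comparison, 192 of 2617 probes were higher and 113 lower in infected RNA, 11.7% in all. Over 3-fold, 30 were higher and 2 lower. With slide as a block the counts were 196 and 115. The arrays of slide 3 alone gave 196 and 110, and those of slide 4 alone 201 and 129. Slide 2 held only 1 array per orientation, which left no spread to test.

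The dye comparison asked how far the Cy5 over Cy3 ratio departs from what infection explains. The dye effect passed the threshold for 2 of 2617 probes, R1__300 and R1__308, named here after their values were seen. R1__300 was 1.56-fold brighter in Cy5 (log2 0.64 ± 0.06 SE, 10 arrays) with a Bonferroni-adjusted p of 0.000425. R1__308 was 1.57-fold brighter in Cy5 (0.65 ± 0.06) with a Bonferroni-adjusted p of 0.000661. At an unadjusted p under 0.05 there were 828 probes, and 409 after Benjamini-Hochberg adjustment with no fold minimum. The standard deviation of the dye effect over probes was 0.09 on the log2 scale, against 0.44 for infection. Loess within arrays had already removed any dye bias common to probes of like brightness. Only the remainder particular to a probe could thus be seen, and the size of the dye bias before normalization was not tested. Fitted separately, the 2 orientations called 289 and 291 probes. They shared 217 of 363 called in either, 59.8%, where independent lists would share 17.5 probes, and none was called with opposite signs. At folds over 2 and 3 the share was 72.2% and 68.6%. With a Bonferroni p of 0.01 it was 53.2%, 70.1% and 68.6% at folds over 1.5, 2 and 3.

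The comparison of labelling approaches covered 2613 probes. One-colour and two-colour calls had 164 probes in common of 376 called in either, 43.6%, where independent lists would share 13.7, and none had opposite signs. The share was 47.7% at folds over 2 and 56.1% over 3. With a Bonferroni p of 0.01 it was 42.0%, 43.1% and 48.8%. Of the one-colour calls, 103 of 117 higher and 61 of 119 lower probes were called the same way in the two-colour fit. Log2 ratios of the 2 approaches had a Pearson correlation of 0.865 and a Spearman correlation of 0.837 across probes, and two-colour ratios had a slope of 0.739 on one-colour ratios. Noise in the one-colour ratios by itself lowers such a slope, so it does not show that two-colour ratios were smaller. Among the 164 shared calls, the one-colour ratio was the larger in size for 91, and the median size ratio of one-colour over two-colour was 1.03. Over the 164 shared calls the Pearson correlation was 0.947, but choosing probes with large ratios in both fits by itself tends to raise it. The ratio itself differed between the approaches, at a Bonferroni-adjusted p under 0.05 and a difference over 1.5-fold, for 22 probes, 6 more positive and 16 more negative in the one-colour fit. In 17 of them the one-colour ratio was the larger in size, and in 6 the signs were opposite. Without the fold minimum 88 probes differed, 390 after Benjamini-Hochberg adjustment, and 778 at an unadjusted p under 0.05. With the fold minimum the count was 13 with quantile scaling, 12 with normexp and 58 without the 6 arrays that stood apart. R1__466 was among the 22, and its difference depended on its control level near background. Of the 22, however, 18 were well above background on all control arrays. The approaches also differed in RNA amount and in scaling, and the cause of the differences was not tested.

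**Figure D4:**
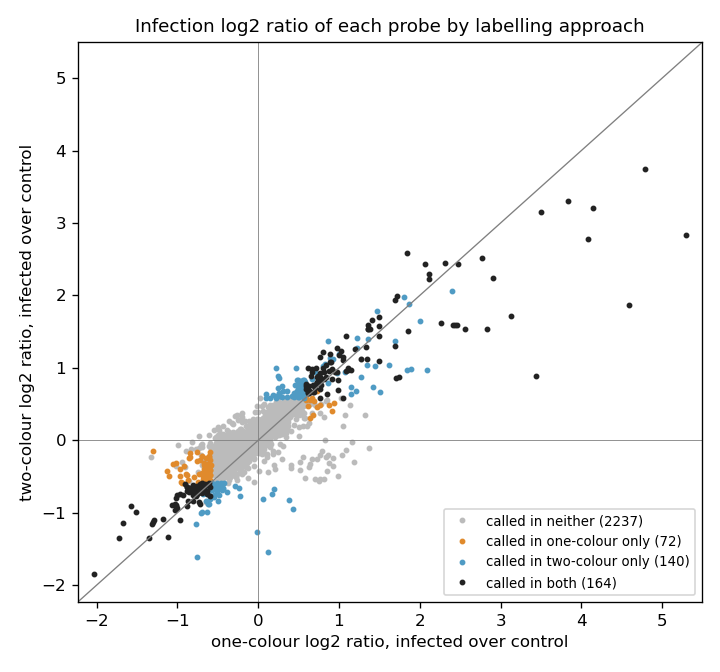
One-colour (horizontal axis) and two-colour (vertical axis) log2 ratio of infected over control for 2613 probes, coloured by where the probe was called, with the line of equality. The 164 probes called in both had the same sign in both fits, with a Pearson correlation of 0.947 and some far from the line. Choosing probes with large ratios in both fits by itself tends to raise this correlation.

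**Figure D5:**
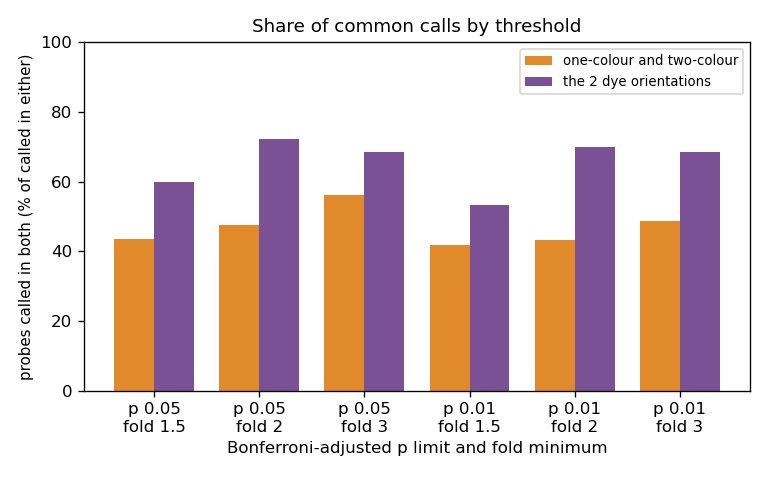
Share of probes called in both sets among those called in either (vertical axis, percent) by Bonferroni-adjusted p limit and fold minimum (horizontal axis). The orange bars compare one-colour with two-colour calls, from 42.0% to 56.1%, and the purple bars compare both dye orientations, from 53.2% to 72.2%.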

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

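Chosen only after results were seen were the tests for infected RNA in control arrays and for a dye effect of each slide, and the limits on infected shares and on probes outside the range were added once earlier values for these arrays were known.

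The search for samples far from the others covered 31 groups of values, and chance flags about 1 in 20. The 15 infected one-colour arrays were left out of it, as their group was too large for the rule. The search found 8. Control 4 stood apart in outlier spots (794, next 304), in the spread among spots of a probe (standard deviation 0.33 on the log2 scale, next 0.08) and in deposited values kept (1063, next 10911). A central patch of this array was dim: in the dimmest cell of an 8 by 6 grid, spots fell by 1.34 on the log2 scale, 2.54-fold, and the patch covered 1122 spots, 8.26% of the fish spots. Both two-colour arrays of slide 2 stood apart in median correlation with their group (0.793 in the Cy5 and 0.774 in the Cy3 orientation, next 0.917 and 0.923). Among two-colour arrays, Cy5 replicate 3 had few deposited values (8197, next 10558) and Cy3 replicate 2 many outlier spots (639, next 411). Control 2 had R1__450 at -1.63, next -5.64.

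The ratio differed between labelling approaches for 22 probes, by a test of the difference itself, and 2 probes had a dye effect. Both counts came from limma fits at a Bonferroni-adjusted p under 0.05 and a fold over 1.5. For the dye effect, the fold limit applied to the Cy5 over Cy3 ratio. The infection ratio differs between orientations by 2 times the dye effect on the log2 scale, so the 2 limits were not alike. At an unadjusted p under 0.05 there were 778 and 828. The count of 22 became 13, 12 and 58 with quantile scaling, with normexp and without the 6 arrays that stood apart.

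Random splits of the arrays gave no calls, but they cannot exclude chance differences between fish or pools. Arrays were shuffled and not fish, and the control RNA came from 1 pool. A shuffled split also puts the infection difference into the spread within groups, so few calls were likely beforehand. Of 100 splits of the 22 one-colour arrays into 15 and 7, only 1, the real one, gave 117 higher probes, and only 1 gave 119 lower ones, with 0 as the highest of the others. Of 100 splits of the 10 two-colour arrays into 5 and 5, only 1, the real one, gave 305 calls, and the highest other was 0. At an unadjusted p under 0.05 in limma, the real splits gave 1716 and 1944 probes and the highest others 910 and 968.

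Control 2 and infected 7 deviated from the other arrays of their groups together (r 0.756 across probes, standard deviations 0.81 and 0.64 on the log2 scale, against at most 0.27 for the 18 arrays that did not stand apart). Scaling that depends on brightness was argued against, since the correlation was 0.715 after the trend with level was removed, as was uneven hybridization, since spots from the upper part of one array and the lower part of the other still correlated at 0.758. A swap of their labels was argued against by the position of infected 7, at 1.1 on an axis from control (0) to infected (1). Infected RNA stays open for control 2 alone. Its position was 0.621, past the midpoint, and its deviation correlated with the infection ratio at 0.600. Its median infected shares over higher and lower probes were 0.137 and 0.050, a gap of 0.087 with a bootstrap SE of 0.074. With both shares this low, a gap within the limit was likely beforehand, so it does not speak for infected RNA. Of called probes, 21.6% lay over 0.5 (log2) outside the range between the group means (binomial SE 2.04). This was near the limit of 20% set for excluding infected RNA. The 18 arrays had at most 1.23% outside, control 4 had 9.31% and control 7 had 10.0%. Infected RNA in control 2 leaves infected 7, with 19.6% outside the range, without an account, so it is not the whole cause of the joint deviation. A difference between RNA extractions, or RNA of another source in both, stays open too. The series text gives 1 control pool, so a difference between pools could bear on infected 7 but not on control 2. No biological explanation was tested, because the labels tie no array to a pool.

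Control 4 and control 7 also deviated together (r 0.795). Control 2 shared part of their deviation (r 0.501 with control 4 and 0.364 with control 7), but infected 7 hardly did (0.081 and -0.026). On the axis from control to infected, control 4 and control 7 stood at 0.450 and 0.432. For the joint deviation of control 4 and control 7, the dim patch was argued against as the cause, since their correlation was 0.832 without its spots. Brightness-dependent scaling was argued against as well, since their correlation was 0.853 after the trend was removed. Infected RNA as the whole cause in both would give 1 share of the infected signal for probes that rise and probes that fall. The median shares over higher and lower probes were 0.332 and 0.711 in control 4 and 0.256 and 0.670 in control 7, a gap of at least 0.380 with a bootstrap SE of 0.071, which argues against it, although their deviations did correlate with the infection ratio at 0.593 and 0.561. A difference between extractions or labellings stays open, and no biological explanation was tested, as all controls came from 1 pool. Control 2, 4 and 7 also had the lowest 75th percentiles of the one-colour arrays, and whether this was linked to their deviations was not tested.

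Both two-colour arrays of slide 2, of opposite orientation, shared a dye deviation (r 0.890). Uneven hybridization was argued against, since upper spots of one array and lower spots of the other correlated at 0.869, and base composition with brightness explained 2.53% of its variance. Whether each slide has a dye effect of its own stays open: on slides 3 and 4 alone, residuals of opposite-orientation pairs had a median correlation 0.377 higher on the same slide than on different slides, but of the 6 arrangements of the arrays over those slides, the real one included, 2 gave a gap as large, the other 0.693. A share under 0.05 cannot be reached with 6 arrangements. Batches of labelled RNA shared within a slide stay open as well, and no biological explanation was tested.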

How the results depend on the processing

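Chosen after the data had been seen were the fits without arrays that stood apart, the median of spots, dim patches left out, scan as a block, single slides for two-colour arrays, slide as a block for the difference between approaches, and the 14 arrays without a block. Under the alternatives 162 values stayed on their side, 43 moved and 1 reversed.

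The 4 named probes kept their sign and a Bonferroni-adjusted p under 0.05 in limma under all 6 alternatives run for each: R1__466 from 2.83 to 6.09, R1__450 from 3.75 to 5.59, R1__2884 from -2.32 to -1.81 and R1__1137 from -2.09 to -1.35. The two-colour fit among the 6 could not fail, since the rule for named probes required a call with the same sign there. The others refitted the one-colour arrays from which the probes were chosen. The 2 shares of common calls stayed within 1.5 times of their value under all alternatives (42.0% to 63.3% between approaches, 46.5% to 72.2% between orientations).

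One-colour calls, 117 higher and 119 lower, became 180 and 74 with the deposited table. That table also lacked filtered spots (2555 probes tested, 1063 values on control 4) and was scaled on 678 spots, and which of these moved the calls was not tested. Its median ratio was higher by 0.11 on the log2 scale, so the split of directions is not settled. They were 192 and 192 with array weights and 210 and 198 without control 2, 4 and 7 and infected 7. The cause was not tested. Single slides, with fewer arrays, gave 33 and 48 (slide 1), 15 and 0 (slide 2), 69 and 16 (slide 3) and 3 and 0 (slide 4). At an unadjusted p under 0.05 in limma, slides 2 and 4, which held control 2, 4 and 7, had 575 and 294 lower probes. Ratios of each slide correlated with the rest at 0.764 to 0.912 across probes. Slides 1 and 3 held 1 control each, assumed to vary like infected arrays. Benjamini-Hochberg adjustment with no fold minimum gave 627 and 1013. Folds over 2 and 3 gave 51 and 24, and 29 and 3, and with a Bonferroni p of 0.01 47 and 23, and 26 and 3. Leaving out 1 control array gave 106 to 132 higher and 105 to 136 lower.

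With replicate number as a block, over 14 arrays, 39 were higher and 41 lower, and the same 14 arrays without the block gave 80 and 93. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.247 to 0.220, 2 of 7 over 0.1, and 0 of 7 correlated best with their own number.

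Two-colour calls, 192 and 113, became 71 and 16 at folds over 2, and 30 and 2 over 3, at either Bonferroni p. Leaving out 1 array gave 189 to 196 and 109 to 118, and 46.5% to 57.9% shared between orientations. Slide 3 alone had 0 probes with a dye effect in limma, with 834 at an unadjusted p under 0.05. Aquantile changed no ratio, as it acts on mean levels.

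Probes whose ratio differed between approaches, 22, became 13 with quantile scaling, 12 with normexp and 58 without the 6 arrays that stood apart, which also raised the correlation of 0.865 to 0.931. The cause was not tested. As ratios to the control mean, the infected median correlation was 0.923 and the control one -0.478, which follows from centring the controls on their own mean; without control 2, 4 and 7 it was 0.997 as levels. The share of slide, 17.5%, became 11.7% with quantile scaling and 32.7% without infected 7, and the cause was not tested.

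Gene lists were not tested, for want of gene names. Signal over background limits R1__466, which was well above background on 1 of 7 controls.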

Other observations

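The comparison in this part was chosen after the data had been seen. Among the fish probes, 3 pairs shared a stretch of 25 bases on the same strand. The members of a pair differed by at most 0.05 in the one-colour log2 ratio.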
